A study of Homo sapiens with 4 samples.

How the data were processed

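Messenger RNA was profiled on Illumina bead arrays in LNCaP cells, a human prostate cancer line, 48 h after transfection with 50 nM of the microRNA miR-31 or of a control microRNA, miR-NC. There were 2 arrays per group, each hybridised with biotin-labelled cRNA made from TRIzol-extracted total RNA, per the labels' protocols. The labels number the arrays as repeats and do not say whether repeats came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series' design text also names 21 pairs of prostate tissues profiled for microRNAs; these were not analysed here.

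The starting table held, per the file headers, non-normalized signal intensity for 47231 probes on each array, on a linear scale and with no negative value. BeadStudio is named in the submitters' processing notes; its version, the bead summarisation and the background setting are not given in the sources used here. Beside each intensity the deposited table holds a score that the file headers call a detection p-value. The values run the other way, with the brightest probes at 1 and the dimmest at 0, so the detection p used here was 1 minus that score. A second table holds the authors' normalized intensity values for the same probes. Its 4 columns had the same median of 14.3 and about 25.1% of values at or below 0, and each column kept the rank order of its own array (rank correlation 0.999999). These values were therefore taken as background-subtracted, linear and normalized to a common distribution; the method behind them is not stated in the sources used here. They carry no centring on genes and no ratio direction, and they served as an alternative.

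Array columns were matched to samples by name. Intensities were processed with limma 3.58.1 in R 4.3.3. The neqc procedure estimated the background from the detection p-values, corrected it by a normal-exponential model, added an offset of 16, applied quantile normalization and took log2. A probe was tested when its detection p was under 0.05 on at least 2 of the 4 arrays, whatever their group. This kept 18354 probes (38.9%). Differences between miR-31 and miR-NC arrays were fitted with lmFit and eBayes with an intensity trend, tested two-sided, and adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 7.19. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333, so every call rests on the spread that limma shares across probes. The number of arrays limits the precision of all values. Errors of log2 changes are standard errors from that fit, and errors of group means are standard deviations of 2 arrays.

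Probes were named from the platform annotation supplied with the series. Of the 47231 probes, 30113 had 1 gene symbol, 8 had several and 17110 had none in that table; 30074 were matched to current symbols by Entrez identifier, giving 20046 distinct genes. A gene was represented by its tested probe with the highest mean over all 4 arrays, which gave 10754 genes. Where that probe was not detected on either array of a group, the fold is given as "at least", computed from the mean of the brighter group against, per array, the higher of the lowest signal among detected probes and the probe's own signal.

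Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 19 lists, and each list was also given the count of members past the threshold when adjustment was made over the list alone. The tests, the 19 lists, the rule for named genes and the alternatives were fixed before the data were examined, except the form of 1 alternative given below. Named genes were the measured members of the list of miR-31 targets named for this study; the 10 genes with the largest fold in each direction among those past the threshold whose arrays did not overlap between groups and which were detected on both arrays of the brighter group; and, in each list, up to 4 members with the smallest p. This gave 81 genes. Genes named outside the rule are identified as such.

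The alternatives were no background correction, an offset of 50, median alignment or cyclic loess in place of the quantile step, the authors' normalized values, no filter, detection p under 0.01 on all 4 arrays, no variance trend, the replicate number as a block, each array left out in turn, a threshold of 0.1, genes counted in place of probes, the mean of a gene's probes, and, for lists, camera with an estimated correlation and fry. The authors' values had been planned for use on the log2 scale as they are; they proved to be linear, and raising them to a floor of 16 before log2 was chosen after they were seen. A planned test of genes with miR-31 seed sites in their 3′ untranslated regions was not run, because no transcript sequences were used here. Some fixed items, among them 1 of the 19 lists, are not reported here; they stay in the adjustment and in counts over all lists and named genes. Neither a slide nor a scan date was given in the sources used here, so no array batch was tested.

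The procedure was tested on simulated arrays built from the real ones. Of probes changed by a log2 of 0.5, 1 and 2, limma called 2 of 67, 30 of 67 and 50 of 66, with 19184 probes tested, and 0 of its 82 calls were unchanged probes. With no probe changed it called 0 of 19558. The list test called the 1 shifted list and 0 of 19 unshifted lists. Noise was drawn independently for each probe and array. The simulation therefore does not test false calls from genes that vary together or from differences shared across an array. Simulated changes of a log2 of 0.5 were mostly missed. With only 82 calls the adjusted threshold was stricter there than with the 1132 probes called in the real data. The simulated shares therefore do not carry over to the real data. Of the 824 genes past the threshold there, 358 were lower and 116 higher by at least 2-fold, and the rest changed by less.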

Results

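Gene expression was measured in LNCaP cells, an androgen-responsive human prostate cancer line grown in serum-containing medium, after transfection with miR-31 or the control microRNA miR-NC. Each group had 2 arrays. Of the probes, 17982 (38.1%) were detected on miR-NC replicate 1 and 17779 (37.6%) on replicate 2, against 16343 (34.6%) on miR-31 replicate 1 and 19246 (40.7%) on replicate 2. Median signals before normalization were 92.5 and 86.4 in miR-NC and 82.5 and 74.6 in miR-31. After normalization, Pearson's r across probes, which are not independent replicates, was 0.979 between the miR-NC arrays and 0.983 between the miR-31 arrays. Between groups it ranged from 0.953 to 0.973. The transfected RNA itself could not be checked on these arrays. The probe named for the MIR31 gene reads the precursor transcript, not the mature microRNA, and was not detected on any array, with detection p between 0.468 and 0.696.

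The comparison of miR-31 with miR-NC asked which messenger RNAs change when miR-31 is raised in prostate cancer cells. Genes of DNA replication and mitosis were lower in miR-31 cells, led by MCM2, a subunit of the replicative helicase, which fell 7.98-fold. Both lists passed by camera at its preset correlation but not with an estimated correlation (adjusted p = 0.102 for replication and adjusted p = 0.114 for mitotic genes). The estimated correlations were −0.02 for replication and 0.03 for mitotic genes, against the preset 0.01. That form of camera rests on the 2 residual degrees of freedom, which limits its p-values. Of the 10 largest rises, 5 were interferon-stimulated genes, with IFI27 at least 6.63-fold higher. Fold sizes depended on the processing. With no background correction MCM2 fell 4.96-fold and IFI27 was at least 3.60-fold higher. IFI27 was at least 4.17-fold higher with an offset of 50 and at least 10.6-fold with the authors' values. Of 18354 probes tested, 1132 (6.17%) passed the threshold in limma, 385 higher and 747 lower in miR-31 (34.0% higher). At the gene level 824 of 10754 genes passed, 261 higher and 563 lower, and 358 of the lower genes fell by at least 2-fold. The groups did not overlap in 9461 probes (51.5%). The share averages about 33.3% over the 3 possible splits of the arrays. Probes share array effects, so the difference is not a test. The count depended on single arrays and on the normalization: 0 probes passed without miR-31 replicate 1 (3033 at an unadjusted p under 0.05) or without miR-31 replicate 2 (2748), none of the 52 named genes past the threshold kept its call in either case, and 2057 probes passed without miR-NC replicate 2. Without miR-31 replicate 1 the median log2 changes were −1.13 for replication and −1.18 for mitotic genes. Without miR-31 replicate 2 they were −1.28 and −1.15, against −1.27 and −1.17 with all arrays. With arrays aligned on their medians instead of quantile-normalized, 61 probes were higher and 45 lower (57.5% higher), 71 of them shared with the main result. The model mattered as well. Without a variance trend 72 were higher and 287 lower (20.1% higher). With the replicate number as a block 1208 were higher and 1328 lower (47.6% higher).

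The study is known for naming genes of the cell cycle and DNA repair, among them E2F1, E2F2, EXO1, FOXM1 and MCM2, as targets of miR-31. MCM2 had a mean log2 signal of 9.15 ± 0.08 (SD, n = 2) in miR-NC and 6.15 ± 0.06 (SD, n = 2) in miR-31, a log2 change of −3.00 ± 0.22 (SE; limma adjusted p = 0.00102). E2F2, a transcription factor that activates S-phase genes, fell 5.41-fold (log2 change −2.44 ± 0.25, SE; adjusted p = 0.00198). EXO1, an exonuclease of mismatch repair and recombination, fell 5.37-fold (−2.42 ± 0.24, SE; adjusted p = 0.00192). FOXM1, a transcription factor of the G2 and M phases, fell 2.43-fold (−1.28 ± 0.21, SE; adjusted p = 0.0108). The value for E2F1 was −0.76 ± 0.28 (SE), which did not pass the threshold (limma adjusted p = 0.153). Its probe was detected on only 1 miR-31 array. All 5 genes were past the threshold when adjusted over the list alone, which is not independent evidence, since the study may have picked these targets partly on these arrays. The list as a whole was lower by camera (median log2 change −2.42, adjusted p = 1.81e-07), with adjusted p = 0.146 with an estimated correlation. E2F1, E2F2, EXO1 and MCM2 are also in the replication list, and FOXM1 is in the mitotic list. Those lists had median log2 changes of −1.27 and −1.17. The falls of the targets therefore cannot be told apart from a general fall of replication and mitotic genes. With no background correction E2F2 and EXO1 fell 3.15-fold and 3.13-fold. FOXM1 lost its call with arrays aligned on their medians (log2 change −1.38, adjusted p = 0.526).

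DNA replication and E2F-regulated genes fell together. Of 47 tested members, 34 were lower, 0 higher and 13 did not pass the threshold, with 37 lower when adjusted over the list alone. The median log2 change was −1.27, a 2.42-fold fall, or −1.20 with the 2 members not detected in miR-31 taken at their bounds. Besides MCM2, the smallest p-values belonged to UHRF1, which maintains DNA methylation at replication forks (−2.72 ± 0.21, SE), CDC45, a helicase cofactor (−2.14 ± 0.18), and MCM3, another helicase subunit (−1.64 ± 0.15). The 1 member with a positive value was RFC2 (0.72 ± 0.41, adjusted p = 0.345); it was singled out after the values were seen. Camera gave adjusted p = 3.22e-28 for the list, and adjusted p = 0.102 with an estimated correlation. The list shared 4 genes with the study's targets.

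Mitotic and FOXM1-regulated genes fell as well. All 45 tested members had negative values; 35 were lower by the test and 10 did not pass, and all 45 were lower when adjusted over the list alone. The median log2 change was −1.17, a 2.25-fold fall. Examples were STMN1, a microtubule-destabilising protein (−2.35 ± 0.26, SE), MELK, a kinase of proliferating cells (−1.89 ± 0.18), KIF20A, a kinesin of cytokinesis (−1.84 ± 0.21), and NUSAP1, a spindle protein (−1.64 ± 0.17). A second STMN1 probe had a smaller value of −0.48 and did not pass (adjusted p = 0.328); with the mean of its probes STMN1 stood at −1.42. Camera gave adjusted p = 5.20e-30, and adjusted p = 0.114 with an estimated correlation. With arrays aligned on their medians, 7 replication and 1 mitotic members were lower by the test, and without a variance trend 24 and 21; the list medians were −1.27 and −1.28 under median alignment, where MCM3, MELK, KIF20A and NUSAP1 lost their calls.

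**Figure D1:**
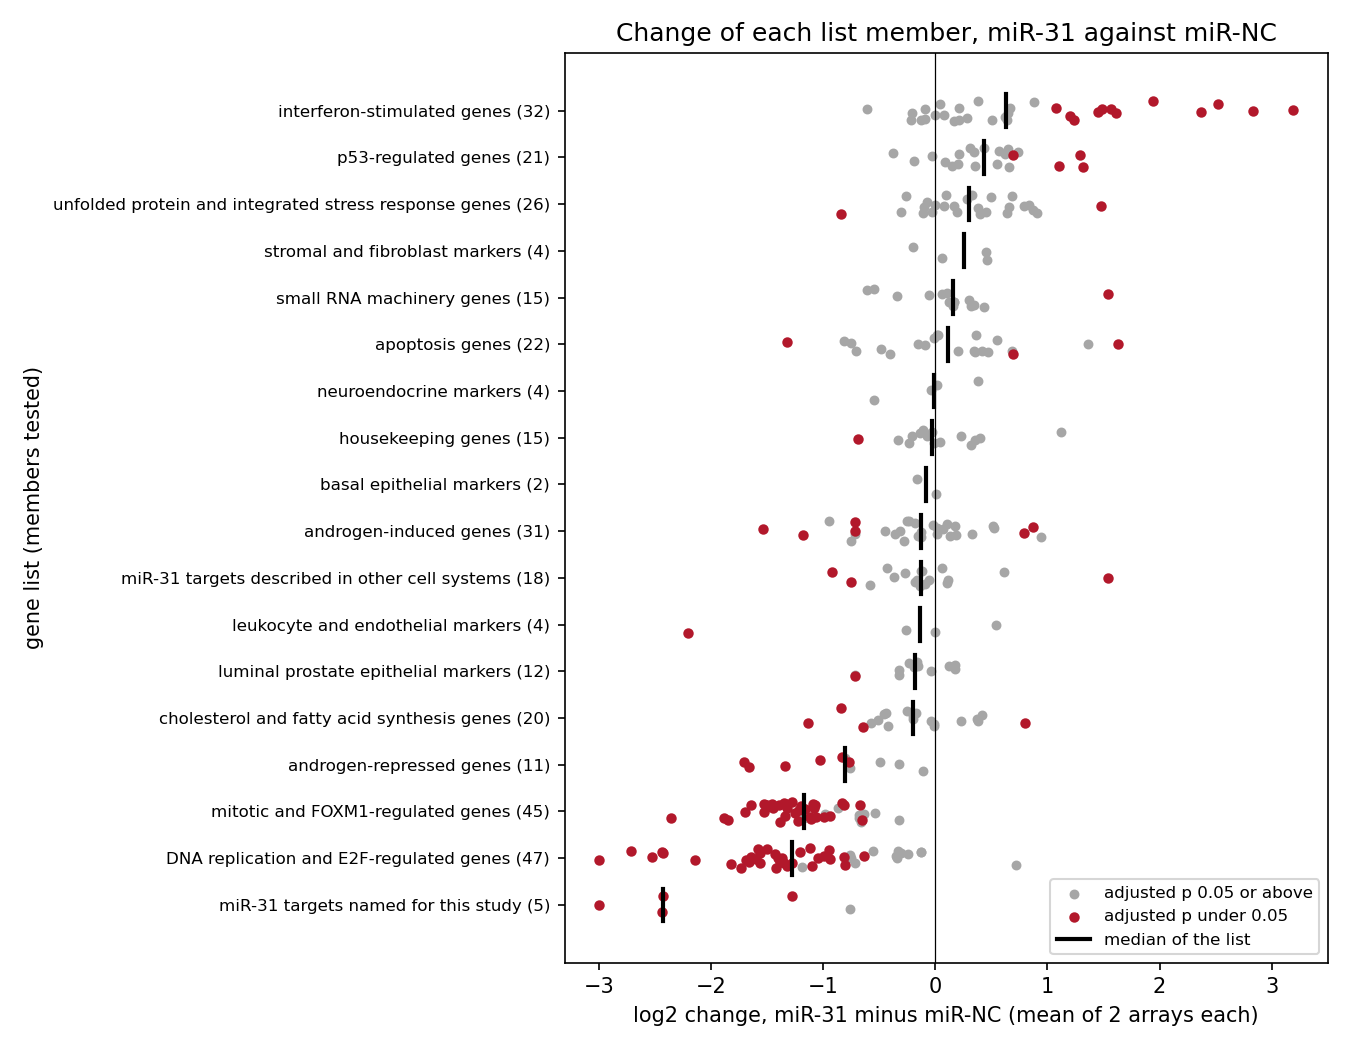
Each point is a tested member of a gene list, placed on the horizontal axis by its log2 change (miR-31 minus miR-NC, means of 2 arrays each), with red for adjusted p under 0.05, grey otherwise, and a black bar for the list's median; the vertical axis gives the lists reported, with the number of members tested. Medians run from −2.42 for the study's targets, over −1.27 for replication and −1.17 for mitotic genes, to 0.63 for interferon-stimulated genes.

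Interferon-stimulated genes were higher in miR-31 cells as a list. Of 32 tested members, 12 were higher, 0 lower and 20 did not pass, with 15 higher and 1 lower when adjusted over the list alone. The median log2 change was 0.63, a 1.55-fold rise, and was the same with the 4 members whose probe was not detected in miR-NC taken at their bounds. Positive values were found for 25 members and negative values for 7. IFI27, an interferon-induced mitochondrial protein, was not detected on either miR-NC array and was at least 6.63-fold higher in miR-31 (adjusted p = 0.00116). OASL, an antiviral protein of the oligoadenylate synthetase family, was at least 6.99-fold higher at its brighter probe, which was not detected on either miR-NC array (adjusted p = 0.00135), while its other tested probe stood at 0.03 and did not pass (adjusted p = 0.978). The OASL bound was 3.77-fold with no background correction, 4.38-fold with an offset of 50 and 11.3-fold with the authors' values. IFIT1 and ISG15, an RNA-binding antiviral protein and a ubiquitin-like modifier, rose by 2.37 ± 0.21 and 1.48 ± 0.14 (SE), and the second IFIT1 probe stood at 0.66 and did not pass (adjusted p = 0.205). With the mean of a gene's probes OASL stood at 1.43 and IFIT1 at 1.51. Camera gave adjusted p = 1.37e-10 for the list, and adjusted p = 0.246 with an estimated correlation.

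p53-regulated genes had a median log2 change of 0.44, a 1.35-fold rise. Of 21 tested members, 4 were higher, 0 lower and 17 did not pass, with 6 higher when adjusted over the list alone. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 2.14-fold (log2 change 1.10 ± 0.14, SE; adjusted p = 0.00474). TP53I3, an oxidoreductase, rose 2.45-fold (1.29 ± 0.21), and TNFRSF10B, a death receptor, rose 1.62-fold (0.70 ± 0.15), with a second probe at 0.70 that did not pass (adjusted p = 0.144). PHLDA3, an inhibitor of AKT signalling, passed at 1.32 ± 0.31 (SE; adjusted p = 0.0425), but its value was 0.76 without miR-NC replicate 1 (adjusted p = 0.0690) and 1.88 without miR-NC replicate 2. Camera gave adjusted p = 5.05e-05 for the list, and adjusted p = 0.246 with an estimated correlation. With arrays aligned on their medians 1 member of this list (CDKN1A) and 8 of the interferon list were higher by the test, and without a variance trend 1 (TP53I3) and 11.

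Apoptosis genes did not pass as a list (22 tested, median log2 change 0.11, camera adjusted p = 0.269), with 2 higher and 1 lower, and the same counts when adjusted over the list alone. PMAIP1, the pro-apoptotic protein NOXA, rose 3.09-fold (1.63 ± 0.18, SE) at its brighter probe, while its second probe stood at 0.71 and did not pass (adjusted p = 0.113). TNFRSF10B rose as given above, and BIRC5, an inhibitor of apoptosis that also acts in mitosis, fell 2.49-fold (−1.32 ± 0.25). BCL2L1, which encodes the anti-apoptotic protein BCL-XL, had a value of 0.69 ± 0.21 and did not pass (adjusted p = 0.0952), but it passed without miR-NC replicate 2 (1.04) and with the replicate block, and stood at 0.35 without miR-NC replicate 1. Genes of the unfolded protein and integrated stress responses were higher as a list, with a median log2 change of 0.30 and camera adjusted p = 0.00139, and adjusted p = 0.229 with an estimated correlation. Of its 26 tested members, 1 was higher and 1 lower, or 7 and 1 when adjusted over the list alone. CHAC1, a glutathione-degrading enzyme induced by ATF4, rose 2.78-fold (1.48 ± 0.23, SE), and CALR, an endoplasmic reticulum chaperone, fell 1.79-fold (−0.84 ± 0.15). The chaperone HYOU1 and the lipoprotein receptor VLDLR had values of 0.90 ± 0.23 and 0.87 ± 0.25 and did not pass (adjusted p = 0.0519 and 0.0742). Both passed with the replicate block and with the mean of a gene's probes. HYOU1 also passed with an offset of 50, at detection p under 0.01 on all 4 arrays and without miR-NC replicate 2 (1.27), and stood at 0.54 without miR-NC replicate 1. VLDLR passed without miR-NC replicate 1 (1.18) and stood at 0.55 without miR-NC replicate 2. PMAIP1, TNFRSF10B, BIRC5, CHAC1 and CALR lost their calls with arrays aligned on their medians, and TNFRSF10B, BIRC5 and CALR also without a variance trend.

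Androgen-repressed genes were lower in miR-31 cells. Of 11 tested members, 6 were lower, 0 higher and 5 did not pass, with 9 lower when adjusted over the list alone, and the median log2 change was −0.80, a 1.74-fold fall. UGT2B17 and UGT2B15, enzymes that inactivate androgens by glucuronidation, fell 3.26-fold (−1.70 ± 0.14, SE) and 3.16-fold (−1.66 ± 0.21); the 2 genes are close paralogs, so which of them changed is uncertain. ACKR3, an atypical chemokine receptor, fell 2.04-fold (−1.03 ± 0.15), and TMEFF2, a transmembrane protein of prostate and brain, fell 1.71-fold (−0.77 ± 0.13). UBE2C, an enzyme of mitotic exit, is in this list and in the mitotic list. Camera gave adjusted p = 2.49e-08, and adjusted p = 0.146 with an estimated correlation. With arrays aligned on their medians 1 member (UGT2B17) was lower by the test, and without a variance trend 3 were, with ACKR3 and TMEFF2 not among them.

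Androgen-induced genes went both ways and did not pass as a list (31 tested, median log2 change −0.13, camera adjusted p = 0.440). There were 2 higher and 4 lower members, or 5 and 6 when adjusted over the list alone. ACP3, prostatic acid phosphatase, fell 2.90-fold (−1.54 ± 0.16, SE), TMPRSS2, a serine protease, fell 1.64-fold (−0.72 ± 0.14), and NCAPD3, a condensin subunit, fell 2.26-fold (−1.18 ± 0.24). ERRFI1, a feedback inhibitor of the EGF receptor, rose 1.82-fold (0.87 ± 0.14). All 4 lost their calls with arrays aligned on their medians, and TMPRSS2, NCAPD3 and ERRFI1 also without a variance trend. Luminal prostate epithelial markers did not pass by camera, which compares a list with other genes (12 tested, median −0.18, adjusted p = 0.269), but were lower by fry, which tests the list's own genes (adjusted p = 0.0216). TMPRSS2 was its 1 member past the threshold, also when adjusted over the list alone, while the protease KLK2 (−0.71 ± 0.24), the transcription factor GRHL2 (−0.32 ± 0.16) and FOLH1, which encodes prostate-specific membrane antigen (−0.32 ± 0.18), did not pass.

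Targets of miR-31 described in other cell systems did not pass as a list (18 tested, median log2 change −0.13, camera adjusted p = 0.440), with 1 higher and 2 lower, or 2 and 2 when adjusted over the list alone. STK40, a kinase-like regulator, fell 1.89-fold (−0.92 ± 0.16, SE) and NUMB, a Notch inhibitor, fell 1.68-fold (−0.75 ± 0.16). DICER1, the enzyme that processes microRNA precursors, rose 2.91-fold (1.54 ± 0.18; adjusted p = 0.00340), and its second probe also passed at 1.38 ± 0.31. With arrays aligned on their medians DICER1 (1.42), STK40 and NUMB lost their calls, and without a variance trend STK40 and NUMB did. NUMB also lost its call with no filter on dim probes. WASF3, an actin regulator, had a value of 0.62 ± 0.19 and did not pass (adjusted p = 0.0999), but it passed with the replicate block. DICER1 was also the 1 member past the threshold among 15 tested small RNA machinery genes (median 0.16, camera adjusted p = 0.290), where 1 was higher and 1 lower when adjusted over the list alone. GEMIN4 (−0.61 ± 0.17), PRKRA (−0.55 ± 0.19) and TARBP2 (0.43 ± 0.23), which act with the Dicer or Argonaute complexes, did not pass; GEMIN4 passed with the replicate block and with the mean of a gene's probes.

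Cholesterol and fatty acid synthesis genes had 1 higher and 3 lower members among 20 tested, or 1 and 6 when adjusted over the list alone, and did not pass as a list (median −0.20, camera adjusted p = 0.167). Without miR-NC replicate 1 the list passed (adjusted p = 0.0336). LSS, which makes lanosterol, fell 2.19-fold (−1.13 ± 0.18, SE) at its brighter probe, with the other at −0.55 (adjusted p = 0.312). SCD, a fatty acid desaturase, fell 1.79-fold (−0.84 ± 0.12), and ACLY, which makes cytosolic acetyl-CoA, fell 1.57-fold at its brighter probe (−0.65 ± 0.13), with the other at −0.32 (adjusted p = 0.316). SC5D, a late sterol desaturase, rose 1.75-fold (0.80 ± 0.14). All 4 lost their calls with arrays aligned on their medians and without a variance trend, and ACLY also with the mean of its probes (−0.48).

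Markers of other cell types were mostly below detection, and none of their lists passed by camera. Neuroendocrine markers had 4 tested members and 0 past the threshold (median −0.01, camera adjusted p = 0.917). Of these, SYT4 (−0.55 ± 0.16, SE) passed when adjusted over the list alone, with the replicate block and with the mean of a gene's probes, and ENO2 (0.38 ± 0.22), UCHL1 (−0.03 ± 0.30) and CHGA (0.02 ± 0.28) did not. Basal epithelial markers had 2 tested members, NGFR (−0.16 ± 0.29) and CAV1 (0.01 ± 0.28), and 0 passed by either adjustment (median −0.08, adjusted p = 0.979). Stromal markers had 4, VIM (0.46 ± 0.18), TAGLN (0.45 ± 0.25), ACTA2 (−0.20 ± 0.18) and FN1 (0.06 ± 0.28), and 0 passed by either adjustment (median 0.26, adjusted p = 0.440). Of 4 leukocyte and endothelial markers (median −0.13, camera adjusted p = 0.440, and lower by fry at adjusted p = 0.0167), VWF, the endothelial blood-clotting factor, fell 4.61-fold (−2.20 ± 0.21), by either adjustment. HLA-DRA (0.54 ± 0.21), CD79A (−0.26 ± 0.31) and CD68 (0.00 ± 0.22) did not pass. Among 15 housekeeping genes, TUBB, a beta-tubulin, passed by either adjustment (−0.69 ± 0.14), but its other tested probe stood at 0.56 and the mean of its probes at −0.06. TUBB lost its call with that mean, with arrays aligned on their medians and without a variance trend. TFRC (0.36 ± 0.16), PGK1 (0.40 ± 0.17) and YWHAZ (0.32 ± 0.14) did not pass, but PGK1 passed without miR-NC replicate 2 (0.59), standing at 0.21 without miR-NC replicate 1 and 0.23 without miR-31 replicate 2, and YWHAZ passed with the mean of its probes (0.73). The housekeeping list did not pass (camera adjusted p = 0.979), with a median of −0.03, a mean of 0.04 and a direction up by camera.

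The largest falls outside the lists were CDK2, the kinase that drives S-phase entry (6.24-fold; log2 change −2.64 ± 0.20, SE), CKAP2L, a spindle protein (4.98-fold; −2.32 ± 0.31), and FANCI, of the Fanconi anemia repair pathway (4.81-fold; −2.27 ± 0.23). MCM10, a replication initiation factor in the replication list, fell 5.78-fold (−2.53 ± 0.26). Among the largest rises, HOPX, a homeodomain-only protein, rose 5.85-fold (2.55 ± 0.26), and the interferon-induced IFIT3 and IFIT2 rose 5.75-fold (2.52 ± 0.30) and 3.84-fold (1.94 ± 0.20), of which IFIT2 lost its call with arrays aligned on their medians. The probes of IFIT3, GET4 and NRBP1 were detected on only 1 miR-NC array, and those of MCM10 and CKAP2L on only 1 miR-31 array. Their folds therefore rest partly on signal near background. With no background correction IFIT3, MCM10, CKAP2L, GET4 and NRBP1 changed by smaller folds of 3.25, 3.25, 2.92, 3.45 and 2.85. With the authors' values IFIT3, MCM10 and CKAP2L changed by larger folds of 9.10, 9.01 and 7.87. The histone gene H2BC8 was not detected in miR-NC and was at least 4.07-fold higher in miR-31 (adjusted p = 0.00404), or at least 2.43-fold with no background correction and at least 6.48-fold with the authors' values. The histone gene H2AC6 (2.81 ± 0.57, SE; adjusted p = 0.0231), GET4, which helps insert tail-anchored membrane proteins (2.39 ± 0.57; adjusted p = 0.0425), and NRBP1, a pseudokinase (2.19 ± 0.44; adjusted p = 0.0227), passed with large spread between arrays. Without miR-NC replicate 1 the values for H2AC6, GET4 and NRBP1 were 1.66, 1.73 and 1.37, and without miR-NC replicate 2 they were 3.98, 3.03 and 3.004. GET4 stood at 3.41 without miR-31 replicate 1 and at 1.41 without miR-31 replicate 2. H2AC6, GET4 and NRBP1 lost their calls with the authors' values and without a variance trend. GET4 also lost its call with no background correction and with cyclic loess.

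**Figure D2:**
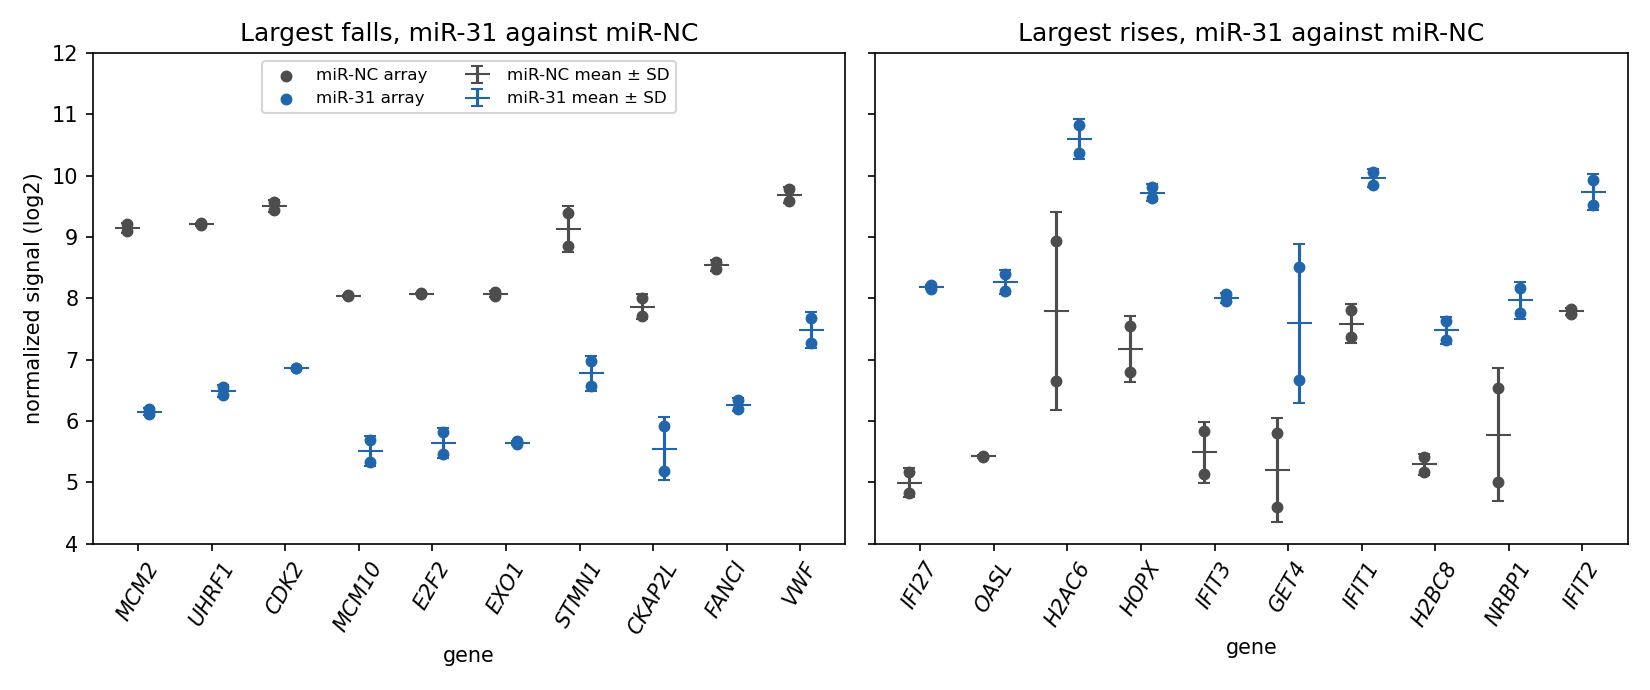
Normalized log2 signal (vertical axis) of the 10 genes with the largest fall (left) and the 10 with the largest rise (right), with a point per array, horizontal bars for group means and error bars for SD (n = 2 arrays per group). MCM2 lies near 9.15 in miR-NC and 6.15 in miR-31, and the miR-NC arrays are widest apart for H2AC6 (SD 1.62).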

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

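The form of 1 alternative, the authors' values raised to a floor of 16 before log2, was chosen after seeing the data, since they were linear; the others were planned. The seed-site test was not run under any setting. All named genes past the threshold had groups that did not overlap, so leaving out an array could hardly turn their sign. None of the 52 named genes past the threshold and none of the 7 lists called by camera turned direction under any setting run, and all 7 lists stayed past the threshold in every camera fit at the preset correlation, each array left out included. The count of probes past the threshold was within 1.5 times the main 1132 with no background correction (378 higher, 739 lower), an offset of 50 (411 and 770), cyclic loess (329 and 698), and detection p under 0.01 on all 4 arrays (441 and 787). Fewer passed with median alignment (106; 61 higher and 45 lower), and with no variance trend (359; 72 and 287). The authors' normalized values gave 241 higher and 577 lower, all 818 shared with the main result, and no filter gave 231 and 564, with 47231 probes tested. A threshold of 0.1 gave 2033 (805 higher, 1228 lower). Leaving out an array gave 0 to 2057 probes (0 to 1120 higher, 0 to 937 lower); these fits leave 1 array alone in its group, which is assumed to vary like the other group. The 0 counts came without either miR-31 array, where 3033 and 2748 probes had an unadjusted p under 0.05. The causes of these shifts were not tested. Named calls were kept by 23 of 52 genes with median alignment, 31 with no variance trend, 47 with the authors' values, 49 with no filter, 50 with cyclic loess and with the mean of a gene's probes, 51 with no background correction, 52 with an offset of 50, and all 42 measured at detection p under 0.01 on all 4 arrays; 48 kept it without miR-NC replicate 1, 52 without miR-NC replicate 2, and 0 without either miR-31 array. Calls lost elsewhere than with median alignment or no variance trend included GET4 (no background correction, cyclic loess, the authors' values), PHLDA3 (cyclic loess, the authors' values, no filter, without miR-NC replicate 1), H2AC6 and NRBP1 (the authors' values), NUMB (no filter, without miR-NC replicate 1), NCAPD3 (without miR-NC replicate 1), and ACLY and TUBB (the mean of a gene's probes). CDKN1A, GET4, H2AC6 and NRBP1 lost theirs without a variance trend. Folds moved by over 1.5 times for 11 of the 52 with no background correction, 7 with an offset of 50 (both smaller), 6 with the authors' values (larger) and 4 with the mean of a gene's probes (smaller).

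With an estimated correlation no list passed: the study's targets and androgen-repressed genes were at adjusted p = 0.146, replication at 0.102, mitotic at 0.114, p53 and interferon at 0.246 and the stress response at 0.229, and 4 lists had an unadjusted p under 0.05. Fry, which tests whether a list's own genes move on balance one way, called 8 lists; p53 missed (adjusted p = 0.0550), and luminal (0.0216) and leukocyte and endothelial markers (0.0167) passed. Lists with no call turned direction: neuroendocrine markers with median alignment (0.993), no filter (0.884) and no variance trend (0.983), and housekeeping genes with the authors' values (0.997), no filter (0.884), detection p under 0.01 on all 4 arrays (0.812) and fry (0.243). With an array left out, cholesterol genes ranged from adjusted p = 0.0336 to 0.375, and housekeeping genes from 0.834 to 0.970, turning without miR-NC replicate 1 (0.854). Basal markers had no member at detection p under 0.01 on all 4 arrays.

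Of the 29 named genes not past the threshold, 7 passed with the replicate block (among them BCL2L1, GEMIN4, HYOU1, SYT4, VLDLR and WASF3), 6 with the mean of a gene's probes (among them GEMIN4, HYOU1, SYT4, VLDLR and YWHAZ), 4 without miR-NC replicate 2 (among them BCL2L1, HYOU1 and PGK1), VLDLR without miR-NC replicate 1, and HYOU1 with an offset of 50 and at detection p under 0.01 on all 4 arrays. Sign changes were found for 7 of the 29. CAV1 stood at −0.00044 with no background correction, −0.03 (−0.0277) with median alignment, −0.02 (−0.0168) with cyclic loess and −0.01 (−0.00651) with the authors' values; UCHL1 at 0.07 (0.0740) with median alignment and 0.08 (0.0844) with cyclic loess; and CD68 at 0.00564 with cyclic loess and 0.20 (0.200) with the mean of its probes. With an array left out, CAV1 ranged from −0.18 to 0.15, CD68 from −0.21 to 0.20, UCHL1 from −0.25 to 0.23, CHGA from −0.14 to 0.17, NGFR from −0.353 to 0.0532, CD79A from −0.532 to 0.0913 and FN1 from −0.0727 to 0.20.

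With the replicate number as a block, 2536 probes passed (1208 higher, 1328 lower) and all 52 named calls were kept. Deviations of same-numbered arrays from their group means correlated at 0.22 across probes; with 2 pairs, and labels that do not say what the numbers share, the numbers were not taken to pair the samples.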

Other observations

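The genes of this paragraph and the next were chosen after their values were seen, from the table of all genes. MYC, a transcription factor of growth, fell by 1.09 on the log2 scale (SE 0.15; limma adjusted p = 0.00521), and SKP2, which targets cell cycle inhibitors for degradation, fell by 1.67 (SE 0.17; adjusted p = 0.00192). PARP1, a DNA damage sensor, fell by 1.69 (SE 0.14; adjusted p = 0.00116). SRD5A1, which makes dihydrotestosterone, fell by 2.10 (SE 0.30; adjusted p = 0.00624), and AMACR, a peroxisomal racemase used as a prostate cancer marker, fell by 1.12 (SE 0.16; adjusted p = 0.00729), with other probes at −1.11 and −0.72, the latter not past the threshold (adjusted p = 0.111). PEX5, the peroxisomal import receptor, fell by 2.12 (SE 0.15; adjusted p = 0.00102).

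The chemokine CXCL8 rose by a log2 of 1.66 (SE 0.23; adjusted p = 0.00547), with a second probe at 1.05 that did not pass (adjusted p = 0.0520). LCN2, a siderophore-binding protein, rose by 1.51 (SE 0.26; adjusted p = 0.0122), and ID2, an inhibitor of differentiation factors, by 1.64 (SE 0.21; adjusted p = 0.00439), with a second probe at 1.70. With arrays aligned on their medians MYC, SKP2, AMACR, CXCL8, LCN2 and ID2 lost their calls, without a variance trend MYC and LCN2 did, and all genes of this paragraph and the one before did so without miR-31 replicate 1 or without miR-31 replicate 2. Replication-dependent histone genes, another group chosen after its values were seen, had 12 of 34 tested members higher and 0 lower, with 27 positive and 7 negative values and a median log2 change of 0.69, a 1.61-fold rise (camera p = 5.97e-10, not adjusted for the choice, and p = 0.0329 with an estimated correlation). The number of higher members was 2 with median alignment, 5 without a variance trend, and 0 without miR-31 replicate 1 or without miR-31 replicate 2, while the list's median lay between 0.50 and 0.84 in these and 9 further alternatives.

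All tests of explanations below were chosen after the results were seen. Replication and mitotic genes were lower in miR-31 by camera at its preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.102 and adjusted p = 0.114). Between the arrays numbered 2 the list medians were −1.25 and −1.14. There the miR-31 array detected more probes (19246 against 17779) and had the higher 95th percentile of signal (1735 against 1575). For that comparison this argues against brightness of the detected probes as the whole cause. The median signal of the miR-31 array, near background, was lower (74.6 against 86.4). Against miR-NC replicate 1 the same miR-31 array detected more probes (19246 against 17982) but had the lower 95th percentile (1735 against 2247). The list medians there were −1.19 and −1.26. Dim probes do not account for the lower values of these lists. Members detected at p under 0.01 on all 4 arrays had medians of −1.27 and −1.17. A direct or indirect effect of miR-31 on proliferation may be the source, but a difference in culture density or transfection load between the groups was not tested and stays open.

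Interferon-stimulated genes were higher in miR-31 by camera at its preset correlation, with 20 of 32 members not past the threshold, but the list did not pass with an estimated correlation (adjusted p = 0.246). The miR-31 replicate 1 array detected fewer probes (16343) than either miR-NC array (17982 and 17779), yet its list medians against them were 0.45 and 0.65, which argues against array brightness as the whole cause. The 4 comparisons of a miR-31 with a miR-NC array gave medians of 0.45 to 0.68, against a response in only 1 of the miR-31 samples. Over members detected at p under 0.01 on all 4 arrays the list median was 0.39. A response to the sequence or preparation of the transfected RNA, apart from targeting, may be the source and stays open, since only 1 control RNA was used.

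Histone genes were higher in miR-31 by camera at its preset correlation, with 12 of 34 members past the threshold. Replication genes, in contrast, were lower by the same test, but not past the threshold with an estimated correlation (adjusted p = 0.102). The miR-31 replicate 1 array detected fewer probes (16343) than either miR-NC array (17982 and 17779). Its list medians against them were 0.89 and 0.62. The histone group was chosen after its values on these arrays were seen, so these medians cannot test array brightness. Genes past the threshold lay in 5 histone families (H1 1 of 2, H2A 3 of 9, H2B 3 of 10, H3 1 of 4, H4 4 of 9). This count cannot show how many transcripts changed within a family. A single changed transcript in each family stays possible. Copies within a family are near-identical, so which genes rose is uncertain. A candidate explanation is a change in the tailed share of histone messages, which carry no poly(A) tail in cycling cells and are poorly primed by oligo-dT; it was not tested.

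For the count of 1132 probes, 1 of the 3 splits of the 4 arrays, the real one, gave as many, and the highest of the other splits gave 0 (346 and 218 probes at an unadjusted p under 0.05 in limma). With 3 splits a share under 0.05 cannot be reached. Each group of the other splits holds a miR-31 and a miR-NC array, so a real difference would widen their spread. Their count of 0 therefore does not show how many calls arise without a difference.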
